A study of Danio rerio with 9 samples.

How the data were processed

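Whole zebrafish embryos of the TU strain were grown at 28 C under 14 h of light and 10 h of dark, exposed to the coal dust extract, grouped by phenotype and lysed at 24 h post fertilisation, per the labels' protocols. RNA was prepared with an RNeasy Mini kit from 50 embryos per phenotype group, and libraries were made with the TruSeq RNA v2 kit with poly(A) selection, per the labels' protocols. Reads were aligned to the Zv9 zebrafish genome with Novoalign (version not given), per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. Gene identifiers, symbols and coordinates are those of the deposited tables, with coordinates 1-based on Zv9.

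The 3 deposited tables, 1 per phenotype against the control, hold raw counts per gene and library, per the file headers. The control counts are the same in all 3 tables, so the 9 libraries were joined into 1 count matrix of 32312 genes, of which 5723 had no read. The authors' tables also hold a score of -10 times the log10 of their p and adjusted p, per the file headers and the values, and a variance-corrected log2 ratio of phenotype over control made by the authors. The authors' test is not named in the sources used here, and their values were used in the closing part alone. FPKM columns (11), variance-corrected count columns (11) and splice columns (9) were not used here. Library totals were 12008832 to 20810487 counts, protein-coding genes took 98.908% of them, and 3 counts corresponded to 0.2498 CPM in the control and 0.1442 CPM in the deepest library. Such floors cover counting error only.

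Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 19835. Counts were normalised with TMM factors, and all 9 libraries entered 1 quasi-likelihood model with group as its term and no block (R 4.3.3, limma 3.58.1). The residual degrees of freedom were 5, the median prior degrees of freedom 12.4 and the common biological coefficient of variation 0.0565. Each phenotype was compared with the control and each pair of phenotypes with each other by two-sided quasi-likelihood F tests, and a joint F test asked for any difference among the 3 phenotypes. P-values were adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. The standard error given with a log2 fold change is its size divided by the square root of F. Fold changes near 0 counts depend on edgeR's prior count, so genes with few control counts are given in CPM. Log CPM values used a prior count of 2.

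Gene lists, 37 in all and holding 1799 entries, covered xenobiotic and stress responses, metabolism, cell and tissue types of the day-old embryo, clock genes and housekeeping groups. Of the entries 1565 matched a symbol of the tables, 73 matched through the reference table of gene names, and 161 were unmatched, ahrra among them, and 84 tested symbols belong to more than 1 gene identifier. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, then with an estimated correlation and with fry. Member counts are given adjusted over all genes and adjusted over the list alone. The tests, lists, naming rule and alternatives were fixed before the data were examined, except those named below or in the closing part as chosen later.

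Genes named in the text follow a rule. For each comparison with the control it takes the 8 largest rises and 8 largest falls that pass, have an assigned symbol, average at least 5 CPM in the higher group and have every phenotype library on the same side of the control. For each pair of phenotypes it takes 6 and 6 without overlap of the groups. It adds up to 4 members with the smallest p from each list, and cyp1a, cyp1b1, cyp1c1, cyp1c2, hmox1, hsp70l, mt2, mdm2 and per2 in every comparison. Some genes and gene lists that the rule or the tests cover are not reported here.

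The whole procedure was tested on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed. For P1 against the control (19406 genes) it recovered 43.3%, 56.7% and 83.3% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 unchanged genes called. For P2 against the control (19423 genes) the shares were 41.8%, 70.1% and 93.9% with 8 called, and for P3 against the control (19417 genes) 38.8%, 65.7% and 93.9% with 13 called. For P1 against P2 (19431 genes) they were 61.2%, 82.1% and 98.5% with 21 called, for P3 against P1 (19411 genes) 68.7%, 82.1% and 89.4% with 9 called, and for P3 against P2 (19427 genes) 58.2%, 79.1% and 95.5% with 14 called.

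Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no filter, a filter of 1 CPM in 2 libraries, a minimum change of 2-fold, a fit of the 2 groups alone, the replicate number as a block, and each phenotype replicate left out in turn. Thinning all libraries to the total of the control, and list tests without P3 replicate 0, were added after seeing the data. Overlaps of calls against the shared control were set beside 20 simulations of unchanged groups. Positions of list medians were taken among 10000 random lists of the same size, matched on mean expression in 50 bins. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.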

Results

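Poly(A) RNA of whole zebrafish embryos (TU strain) was sequenced at 24 h post fertilisation in 9 libraries. Embryos had been exposed from 4 h post fertilisation to 100 mg/L of a methanol extract of coal dust in dimethyl sulfoxide, and the exposed embryos were grouped by malformation before RNA was taken from 50 embryos per group. Deformed tails define P1 (n = 3), deformed yolks P2 (n = 2), and small embryos with extruded yolks P3 (n = 3). The control was 1 pooled library of normal embryos (n = 1). Whether these received the solvent is not given in the sources used here. Total gene counts were 12008832 in the control and 17198110, 14719252 and 15227316 in P1. They were 16267045 and 18358853 in P2, and 16048949, 15520740 and 20810487 in P3. Between 23315 and 24024 genes had a read in each library, and the 10 most abundant genes took 6.43% to 7.3% of the counts.

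The 3 comparisons with the control ask which transcripts accompany each malformation after exposure, and the 3 comparisons between phenotypes ask how the malformations differ. Values are log2 fold changes ± standard error from edgeR, or CPM (counts scaled by library size) ± SD, for Zv9 gene models. A rise or fall is an edgeR adjusted p below 0.05 over 19835 tested genes. Because the control had 1 library, its spread was taken to equal that pooled from the phenotypes. P-values measure only the spread between these samples, which may be technical. Crystallin, heat shock, actinodin, CYP1C and hatching enzyme genes have close copies, so reads shared between copies make their values uncertain, and overlapping genes on opposite strands were not told apart.

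Embryos with deformed tails (P1) had a strong aryl hydrocarbon receptor (AHR) response, the program by which polycyclic aromatic hydrocarbons raise their own metabolism. They also had lower transcripts of lens, skin and pigment, and of muscle, whose list call was lost with an estimated correlation. The AHR-driven cytochrome P450 gene cyp1a (ENSDARG00000026039, chromosome 18, 4974676 to 4985566) was at 4100 ± 83.5 CPM (SD, n = 3) against 119 in the control. It was 34.5-fold higher (5.11 ± 0.11, edgeR adjusted p = 9.4e-16). Its relatives cyp1b1 (ENSDARG00000068934, chromosome 13, 42664264 to 42671929), cyp1c1 (ENSDARG00000058980, Zv9_NA892, 103570 to 106640) and cyp1c2 (ENSDARG00000018298, Zv9_scaffold3548, 298353 to 300627) rose 40.3-fold, 49.5-fold and 30-fold. The sulfotransferase gene sult6b1 (2.97 ± 0.12), the gene tiparp (1.87 ± 0.09), whose product restrains AHR, and the forkhead factor gene foxq1a (3.74 ± 0.21) rose as well. Other large rises were gchfr (3.52 ± 0.3), which encodes a regulator of tetrahydrobiopterin synthesis, and the transporter gene slc16a9b (3.25 ± 0.14). Of 16 AHR genes, 11 rose and 0 fell, or 11 and 1 adjusted over the list alone, with a median log2 fold change of 1.57. Of 21 other xenobiotic metabolism genes, 6 rose and 2 fell, or 7 and 3 adjusted over the list alone, with a median log2 fold change of 0.29. For the AHR and other xenobiotic metabolism lists, camera gave adjusted p = 4.29e-79 and 0.041, or 0.0174 and 0.358 with an estimated correlation.

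Lens, pigment, skin, muscle and matrix genes were lower in P1. The fin fold gene and2 (ENSDARG00000079302, chromosome 2, 31480049 to 31484497), which encodes an actinodin, was 13.1-fold lower (-3.71 ± 0.16, edgeR adjusted p = 4.07e-11). The lens crystallin gene crybb1l1 (ENSDARG00000007576, chromosome 14, 49240144 to 49245598) was 4.63-fold lower, with cryba2a (-1.83 ± 0.14), crygm2d13 (-3.03 ± 0.24) and crygmxl2 (-2.67 ± 0.24). The melanin synthesis genes dct (-1.39 ± 0.1), tyr (-0.96 ± 0.1) and tyrp1b (-1.26 ± 0.15) and the keratin gene krt15 (-3.41 ± 0.23) fell. Of 54 eye and lens genes, 0 rose and 27 fell, or 0 and 31 adjusted over the list alone (median -0.75). Of 45 pigment and neural crest genes, 2 rose and 17 fell, or 2 and 18 adjusted over the list alone (median -0.15). Of 67 epidermis and ionocyte genes, 2 rose and 35 fell, or 4 and 39 adjusted over the list alone (median -0.32). For the eye and lens, pigment and neural crest and epidermis and ionocyte lists, camera gave adjusted p = 2.09e-33, 5.83e-06 and 5.91e-15, or 0.0235, 0.0278 and 0.028 with an estimated correlation. In muscle, the fast myosin light chain gene mylpfb (-1.48 ± 0.11), the Z-disc gene myoz1a (-2.04 ± 0.19) and the calcium store gene casq1a (-0.96 ± 0.1) fell. Matrix genes that fell were and3 (-2.96 ± 0.32), and1 (-1.77 ± 0.14) and col6a3 (-1.44 ± 0.13) and the proteoglycan gene fmodb (-2.67 ± 0.23). Of 75 skeletal muscle genes, 0 rose and 51 fell, or 0 and 56 adjusted over the list alone (median -0.5). Of 70 collagen and matrix genes, 1 rose and 37 fell, or 1 and 41 adjusted over the list alone (median -0.4). For the skeletal muscle and collagen and matrix lists, camera gave adjusted p = 3.14e-23 and 1.32e-22, or 0.187 and 0.172 with an estimated correlation.

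Neuronal genes such as ebf3 (-0.79 ± 0.1), a transcription factor gene, and the neurofilament gene nefm (-0.76 ± 0.11) fell, as did the notochord proteoglycan genes epyc (-0.98 ± 0.12) and acana (-2.01 ± 0.31). Of 69 neuron genes, 0 rose and 21 fell, or 0 and 23 adjusted over the list alone, with a median log2 fold change of -0.29. Of 41 notochord genes, 3 rose and 14 fell, or 5 and 14 adjusted over the list alone, with a median log2 fold change of -0.1. For the neuron and notochord lists, camera gave adjusted p = 1.27e-07 and 0.00937, or 0.187 and 0.182 with an estimated correlation. The lysozyme gene lyz (-1.3 ± 0.15) and the neutrophil peroxidase gene mpx (-1.7 ± 0.21) fell, as did the complement inhibitor gene SERPING1 (-3.04 ± 0.36). The apolipoprotein gene apoa4 (-1.31 ± 0.09) and the retinol carrier gene rbp4 (-0.85 ± 0.08) fell in the yolk and lipid transport list. Of 22 myeloid genes, 0 rose and 5 fell, or 0 and 5 adjusted over the list alone (median -0.11). Of 44 yolk and lipid transport genes, 3 rose and 13 fell, or 3 and 15 adjusted over the list alone (median -0.09). For the myeloid and yolk and lipid transport lists, camera gave adjusted p = 0.041 and 0.000969, or 0.2 and 0.187 with an estimated correlation. The oxygen sensor gene egln3 (-2.28 ± 0.22), the collagen hydroxylase gene p4ha1b (-1.17 ± 0.07) and the muscle phosphofructokinase gene pfkma (-1.74 ± 0.22) fell. Of 49 glycolysis and hypoxia genes, 2 rose and 15 fell, or 3 and 18 adjusted over the list alone, with a median log2 fold change of -0.25. For the glycolysis and hypoxia list, camera gave adjusted p = 0.000127, or 0.338 with an estimated correlation.

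Rises in P1 outside the AHR list covered antioxidant, clock and progenitor genes. The glutathione transferase gene gstp1 (1.62 ± 0.21) and the peroxidase gene prdx1 (0.88 ± 0.14) rose. The haem oxygenase gene hmox1 stood at -0.03 ± 0.1 (edgeR adjusted p = 0.873). The heat shock gene hsp70l stood at 0.571 ± 0.152 CPM against 0.167 in the control (edgeR adjusted p = 0.301). The cell cycle inhibitor gene cdkn1a (0.91 ± 0.16), the damage response gene gadd45aa (1.3 ± 0.19) and the ubiquitin ligase gene mdm2 (0.44 ± 0.1) rose. Of 36 oxidative stress genes, 16 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 0.3). For the oxidative stress list, camera gave adjusted p = 2.11e-07, or 0.216 with an estimated correlation. Of 32 chaperone genes, 12 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.21). Of 35 unfolded protein and integrated stress genes, 8 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.1). For the chaperone and unfolded protein and integrated stress lists, camera gave adjusted p = 0.000459 and 0.0134, or 0.2 and 0.285 with an estimated correlation. Light-driven clock genes per2 (1.74 ± 0.27), cry1a (1.53 ± 0.22) and tefa (1.26 ± 0.18) rose. Of 44 clock genes, 13 rose and 1 fell, or 14 and 2 adjusted over the list alone (median 0.29). For the clock list, camera gave adjusted p = 8.77e-06, or 0.2 with an estimated correlation. The somite precursor factor gene tbx6 (1.27 ± 0.2) and the retinoic acid degrading enzyme gene cyp26a1 (1.07 ± 0.09) rose, while the thrombospondin gene thbs2b (-0.99 ± 0.1) fell. The muscle regulator gene myog (1.32 ± 0.13), the mesoderm factor gene meox1 (0.68 ± 0.11) and the cell fusion gene tmem8c (0.96 ± 0.17) rose. Of 53 tailbud and presomitic mesoderm genes, 9 rose and 3 fell, or 11 and 4 adjusted over the list alone (median 0.19). Of 22 myogenic precursor genes, 5 rose and 0 fell, or 7 and 1 adjusted over the list alone (median 0.1). For the tailbud and presomitic mesoderm and myogenic precursor lists, camera gave adjusted p = 0.000969 and 0.0262, or 0.196 and 0.187 with an estimated correlation.

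Mitochondrially encoded genes such as mt-cyb (0.62 ± 0.08) and mt-co3 (0.45 ± 0.07) rose, and together these genes took 3.4% to 3.68% of the counts in P1 against 2.73% in the control. Of 13 mitochondrially encoded genes, 9 rose and 0 fell, or 11 and 0 adjusted over the list alone (median 0.38). For the mitochondrially encoded list, camera gave adjusted p = 1.27e-07, or 0.187 with an estimated correlation. The sterol reductase gene dhcr7 (0.81 ± 0.14) and the fatty acid desaturase gene fads2 (2.03 ± 0.42) rose. Of 35 lipid synthesis genes, 13 rose and 2 fell, or 16 and 2 adjusted over the list alone (median 0.36). For the lipid synthesis list, camera gave adjusted p = 0.000133, or 0.172 with an estimated correlation. The metallothionein gene mt2 (-1.02 ± 0.11) and the zinc transporter gene slc30a8 (-1.28 ± 0.11) fell. In total 3227 genes (16.3%) changed in P1, 1405 higher and 1822 lower, 706 of them at least 2-fold. In all 3227 every P1 library lay on the named side of the control, which the call itself favours. DESeq2 gave 1913.

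**Figure D1:**
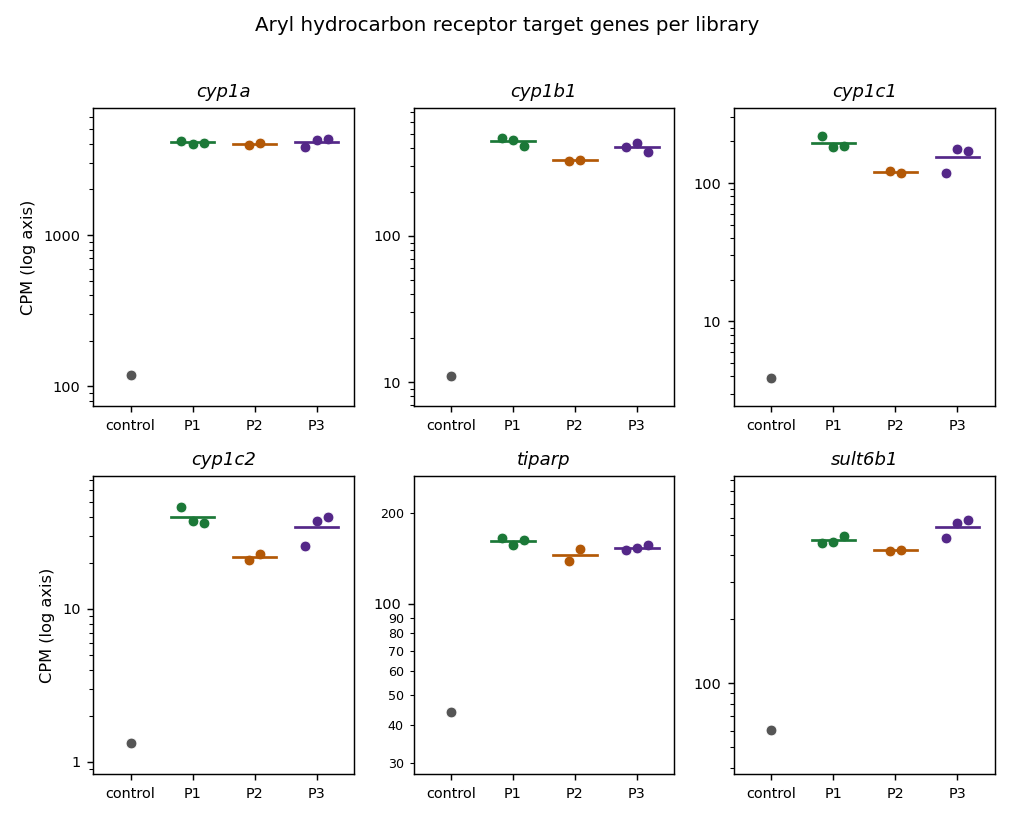
CPM on a log axis of AHR-linked genes in each library, with points for single libraries and lines for the mean of groups with more than 1 library. For cyp1a the control stood at 119 CPM and the group means of P1, P2 and P3 at 4100, 4000 and 4120 CPM.

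Embryos with deformed yolks (P2) had the AHR response, the lowest medians of the lens, muscle, pigment and neuron lists among the 3 phenotypes, and rises of single hypoxia and stress genes such as egln3 and PPP1R15A. Expression of cyp1a was 4000 ± 105 CPM (SD, n = 2), 33.8-fold above the control (5.08 ± 0.11, edgeR adjusted p = 1.28e-15). With it rose cyp1b1 (4.89 ± 0.14), cyp1c1 (4.93 ± 0.28), cyp1c2 (4.03 ± 0.39), sult6b1 (2.81 ± 0.12) and tiparp (1.72 ± 0.09). Of 16 AHR genes, 11 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median log2 fold change of 1.48. Of 21 other xenobiotic metabolism genes, 7 rose and 2 fell, or 7 and 3 adjusted over the list alone, with a median log2 fold change of 0.36. For the AHR and other xenobiotic metabolism lists, camera gave adjusted p = 6.4e-39 and 0.348, or 0.0295 and 0.734 with an estimated correlation. The monocarboxylate transporter family genes slc16a9a (ENSDARG00000013926, chromosome 17, 20483927 to 20496769) and slc16a9b (4.23 ± 0.14) rose, slc16a9a to 22.2 ± 0.296 CPM from 10 counts in the control.

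The lens genes crybb1l1 and mipb, which encodes a lens water channel, were 12.3-fold and 26.6-fold lower, with crybb1 (-2.73 ± 0.14) and crygm2d13 (-4.98 ± 0.32). The melanin genes dct (-2.66 ± 0.11), tyrp1b (-2.55 ± 0.17) and tyr (-1.59 ± 0.11) fell. Of 54 eye and lens genes, 0 rose and 36 fell, or 0 and 38 adjusted over the list alone, with a median log2 fold change of -1.29. Of 45 pigment and neural crest genes, 5 rose and 22 fell, or 5 and 25 adjusted over the list alone, with a median log2 fold change of -0.5. For the eye and lens and pigment and neural crest lists, camera gave adjusted p = 9.05e-41 and 1.55e-11, or 0.0176 and 0.0139 with an estimated correlation. In muscle casq1a (-2.22 ± 0.12), mylpfb (-2.51 ± 0.12) and myoz1a (-3.63 ± 0.24) fell, and among neuronal genes the intermediate filament genes nefm (-2.14 ± 0.12) and prph (-2.0 ± 0.22). Of 75 skeletal muscle genes, 2 rose and 61 fell, or 2 and 64 adjusted over the list alone, with a median log2 fold change of -0.83. Of 69 neuron genes, 0 rose and 46 fell, or 0 and 47 adjusted over the list alone, with a median log2 fold change of -0.53. For the skeletal muscle and neuron lists, camera gave adjusted p = 3.87e-37 and 1.83e-11, or 0.142 and 0.142 with an estimated correlation. The actinodin gene and3 (ENSDARG00000056873, chromosome 10, 23048766 to 23054968) was 64.7-fold lower (-6.02 ± 0.49, edgeR adjusted p = 7.54e-08), with and2 (-4.97 ± 0.2) and and1 (-3.35 ± 0.17). The cartilage matrilin gene matn3a (-4.5 ± 0.49), the calpain gene capn3 (-4.16 ± 0.27) and the proteoglycan gene fmodb (-3.93 ± 0.28) were other large falls. Of 70 collagen and matrix genes, 7 rose and 33 fell, or 11 and 36 adjusted over the list alone, with a median log2 fold change of -0.32. Of 67 epidermis and ionocyte genes, 6 rose and 32 fell, or 9 and 33 adjusted over the list alone, with a median log2 fold change of -0.24. For the collagen and matrix and epidermis and ionocyte lists, camera gave adjusted p = 1.95e-09 and 3.45e-06, or 0.211 and 0.141 with an estimated correlation.

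Hypoxia, integrated stress and heat shock genes moved both ways in P2. The hypoxia-induced genes ankrd37 (2.32 ± 0.15) and egln3 (ENSDARG00000032553, chromosome 17, 9776764 to 9794821, 1.93 ± 0.17) and the kinase gene mknk2b (1.61 ± 0.09) rose, while the phosphofructokinase gene pfkma (-2.73 ± 0.25) fell. The phosphatase subunit gene PPP1R15A (1.67 ± 0.1), which ends the translational arrest of the integrated stress response, and the mTOR inhibitor gene ddit4 (2.37 ± 0.16) rose. Of 49 glycolysis and hypoxia genes, 11 rose and 17 fell, or 12 and 19 adjusted over the list alone, with a median log2 fold change of -0.2. Of 35 unfolded protein and integrated stress genes, 6 rose and 7 fell, or 6 and 8 adjusted over the list alone, with a median log2 fold change of -0.03. For the glycolysis and hypoxia and unfolded protein and integrated stress lists, camera gave adjusted p = 0.549 and 0.459, or 0.905 and 0.802 with an estimated correlation. The mean of the latter list was 0.08. The cell cycle genes cdkn1a (1.94 ± 0.15) and ccng1 (1.02 ± 0.13), the ubiquitin ligase gene mdm2 (0.52 ± 0.11) and the cell death gene bbc3 (1.95 ± 0.18) rose, as did the survival gene mcl1b (1.43 ± 0.1). The autophagy receptor gene sqstm1 (1.4 ± 0.14) and gstp1 (1.84 ± 0.22) rose, and hmox1 (-0.52 ± 0.11) fell. Of 36 oxidative stress genes, 21 rose and 2 fell, or 21 and 3 adjusted over the list alone, with a median log2 fold change of 0.32. For the oxidative stress list, camera gave adjusted p = 9.61e-06, or 0.331 with an estimated correlation. The small heat shock gene hspb9 (-2.73 ± 0.23) and the metal genes mt2 (-1.47 ± 0.12) and slc30a8 (-1.33 ± 0.11) fell. Of 32 chaperone genes, 6 rose and 8 fell, or 7 and 9 adjusted over the list alone, with a median log2 fold change of 0.03. For the chaperone list, camera gave adjusted p = 0.549, or 0.868 with an estimated correlation. The mean of the chaperone list was -0.2.

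Clock genes per2 (2.03 ± 0.28), cry1a (1.74 ± 0.22), tefa (1.59 ± 0.19) and nfil3-6 (2.64 ± 0.26) rose. In the tailbud list tbx6 (2.24 ± 0.19) and cyp26a1 (1.68 ± 0.09) rose and the FGF-binding protein gene FGFBP3 (-1.38 ± 0.1) fell. Of 44 clock genes, 23 rose and 2 fell, or 26 and 2 adjusted over the list alone, with a median log2 fold change of 0.62. Of 53 tailbud and presomitic mesoderm genes, 22 rose and 5 fell, or 26 and 6 adjusted over the list alone, with a median log2 fold change of 0.37. For the clock and tailbud and presomitic mesoderm lists, camera gave adjusted p = 1.09e-08 and 0.00029, or 0.155 and 0.167 with an estimated correlation. The cohesin acetyltransferase gene esco2 (0.47 ± 0.08) and the cyclin gene ccne2 (0.49 ± 0.09) rose with other cell cycle genes. Of 83 cell cycle genes, 35 rose and 1 fell, or 38 and 2 adjusted over the list alone (median 0.21). Camera called this rise in P1, P2 and P3 (adjusted p = 5.48e-06, 1.99e-05 and 0.0177, or 0.216, 0.286 and 0.491 with an estimated correlation). The sterol regulator gene insig1 (1.47 ± 0.16) and the isoprenoid synthesis gene idi1 (0.76 ± 0.09) rose. Of 35 lipid synthesis genes, 15 rose and 5 fell, or 15 and 5 adjusted over the list alone (median 0.41). For the lipid synthesis list, camera gave adjusted p = 0.00221, or 0.167 with an estimated correlation.

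Liver and yolk transcripts were lower, with falls of rbp4 (-2.2 ± 0.09) and apoa4 (-1.46 ± 0.09), the plasma protein gene ambpl (-1.3 ± 0.12) and the fibrinogen gene fgg (-1.05 ± 0.1). Of 34 endoderm and liver genes, 3 rose and 12 fell, or 4 and 12 adjusted over the list alone, with a median log2 fold change of -0.17. Of 44 yolk and lipid transport genes, 6 rose and 22 fell, or 6 and 24 adjusted over the list alone, with a median log2 fold change of -0.27. For the endoderm and liver and yolk and lipid transport lists, camera gave adjusted p = 0.00133 and 4.75e-07, or 0.211 and 0.115 with an estimated correlation. The myeloid genes lyz (-2.11 ± 0.17) and mpx (-2.81 ± 0.25) fell. Of 22 myeloid genes, 2 rose and 7 fell, or 2 and 7 adjusted over the list alone, with a median log2 fold change of -0.02. For the myeloid list, camera gave adjusted p = 0.0442, or 0.211 with an estimated correlation. In total 5916 genes (29.8%) changed, 2822 higher and 3094 lower, 1786 of them at least 2-fold. In all 5916 both P2 libraries lay on the named side of the control, which the call itself favours. DESeq2 gave 3769.

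Small embryos with extruded yolks (P3) had the AHR response, lower lens, muscle and matrix transcripts, and higher mitochondrially encoded transcripts. With an estimated correlation the AHR and lens list calls held, and those of the other 3 lists were lost. In P3 cyp1a was at 4120 ± 260 CPM (SD, n = 3), 34.7-fold above the control (5.12 ± 0.11, edgeR adjusted p = 9.23e-16). Its relatives and co-regulated genes cyp1b1 (5.19 ± 0.14), cyp1c1 (5.3 ± 0.27), cyp1c2 (4.69 ± 0.36), sult6b1 (3.18 ± 0.12) and tiparp (1.8 ± 0.09) rose. Of 16 AHR genes, 11 rose and 1 fell, or 11 and 2 adjusted over the list alone, with a median log2 fold change of 1.62. Of 21 other xenobiotic metabolism genes, 10 rose and 1 fell, or 10 and 5 adjusted over the list alone, with a median log2 fold change of 0.45. For the AHR and other xenobiotic metabolism lists, camera gave adjusted p = 4.68e-53 and 0.0136, or 0.0219 and 0.358 with an estimated correlation. The angiotensinogen gene agt (ENSDARG00000016412, chromosome 13, 24212332 to 24219766) was at 16.7 ± 2.37 CPM from 4 counts in the control, and the collagenase gene mmp13a (2.63 ± 0.3) rose 6.18-fold. The actinodin gene and2 was 35.2-fold lower, with and3 (-3.93 ± 0.34) and and1 (-2.85 ± 0.15).

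Lens genes crybb1l1 (-2.94 ± 0.14), crybb1 (-2.36 ± 0.13), crygm2d13 (-3.86 ± 0.26) and mipb (-3.41 ± 0.23) and the melanin genes dct (-1.72 ± 0.1) and tyr (-1.07 ± 0.1) fell. Of 54 eye and lens genes, 0 rose and 32 fell, or 0 and 34 adjusted over the list alone, with a median log2 fold change of -0.95. Of 45 pigment and neural crest genes, 5 rose and 20 fell, or 7 and 20 adjusted over the list alone, with a median log2 fold change of -0.26. For the eye and lens and pigment and neural crest lists, camera gave adjusted p = 7.73e-43 and 7.28e-06, or 0.0211 and 0.0279 with an estimated correlation. The muscle genes mylpfb (-2.0 ± 0.11) and casq1a (-1.7 ± 0.11) and the actin gene acta1b (-0.97 ± 0.08) fell. P3 replicate 0 lay below the other 2 P3 replicates in the skeletal muscle list, by a median log2 of -0.39, and less so in the matrix (-0.17), hypoxia (-0.18), erythroid (-0.14) and neuron (-0.14) lists. In a test chosen after seeing the data, camera without that library still called these lists lower, with adjusted p = 1.84e-43, 4.54e-28, 0.00213, 0.017 and 2.48e-06, but no call held with an estimated correlation (0.0776, 0.0794, 0.32, 0.319 and 0.0833). Matrix genes that fell were col6a3 (-1.73 ± 0.13) and fmodb (-3.86 ± 0.25) and the skin anchoring collagen gene col17a1a (-3.16 ± 0.3). Of 75 skeletal muscle genes, 1 rose and 57 fell, or 1 and 61 adjusted over the list alone, with a median log2 fold change of -0.72. Of 70 collagen and matrix genes, 0 rose and 43 fell, or 0 and 48 adjusted over the list alone, with a median log2 fold change of -0.5. For the skeletal muscle and collagen and matrix lists, camera gave adjusted p = 1.15e-33 and 2.85e-28, or 0.138 and 0.116 with an estimated correlation. Of 67 epidermis and ionocyte genes, 8 rose and 37 fell, or 12 and 38 adjusted over the list alone, with a median log2 fold change of -0.36. Of 69 neuron genes, 0 rose and 30 fell, or 0 and 38 adjusted over the list alone, with a median log2 fold change of -0.35. For the epidermis and ionocyte and neuron lists, camera gave adjusted p = 6.52e-11 and 8.93e-08, or 0.0507 and 0.209 with an estimated correlation.

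Mitochondrially encoded genes such as mt-cyb (0.89 ± 0.08) and mt-co3 (0.64 ± 0.07) rose, and took 3.99% to 4.21% of the counts in P3. The red cell genes cahz (-0.93 ± 0.08), rhag (-0.93 ± 0.09) and slc4a1a (-0.9 ± 0.1), which encode carbonic anhydrase, an ammonium channel and an anion exchanger, fell. Of 13 mitochondrially encoded genes, 12 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a median log2 fold change of 0.56. Of 32 erythroid genes, 3 rose and 11 fell, or 3 and 12 adjusted over the list alone, with a median log2 fold change of -0.18. For the mitochondrially encoded and erythroid lists, camera gave adjusted p = 1.03e-11 and 0.00654, or 0.124 and 0.288 with an estimated correlation. The liver regulator gene hnf4a (1.32 ± 0.15) and the retinol-binding gene rbp2a (1.16 ± 0.15) rose, while rbp4 (-1.66 ± 0.08) and apoa4 (-1.36 ± 0.09) fell. Of 34 endoderm and liver genes, 10 rose and 3 fell, or 11 and 3 adjusted over the list alone, with a median log2 fold change of 0.15. Of 44 yolk and lipid transport genes, 10 rose and 12 fell, or 10 and 14 adjusted over the list alone, with a median log2 fold change of 0.01. For the endoderm and liver and yolk and lipid transport lists, camera gave adjusted p = 0.0704 and 0.0919, or 0.448 and 0.431 with an estimated correlation. The mean of the latter list was -0.13, with camera pointing down. The glucose transporter gene slc2a1a (1.25 ± 0.15) rose while egln3 (-1.85 ± 0.21) and pfkma (-2.43 ± 0.22) fell. Of 49 glycolysis and hypoxia genes, 8 rose and 19 fell, or 9 and 21 adjusted over the list alone, with a median log2 fold change of -0.32. For the glycolysis and hypoxia list, camera gave adjusted p = 0.000461, or 0.432 with an estimated correlation.

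Stress genes that rose were the leucine sensor gene sesn2 (1.02 ± 0.13), the transcription factor gene atf3 (0.98 ± 0.16), the amino acid transporter gene slc3a2b (0.87 ± 0.1) and ddit4 (1.35 ± 0.16). The genes mdm2 (0.67 ± 0.1), bbc3 (1.24 ± 0.18) and btg2 (0.53 ± 0.08) rose. Of 35 unfolded protein and integrated stress genes, 16 rose and 1 fell, or 17 and 2 adjusted over the list alone, with a median log2 fold change of 0.19. For the unfolded protein and integrated stress list, camera gave adjusted p = 0.000336, or 0.214 with an estimated correlation. Of 32 chaperone genes, 6 rose and 4 fell, or 8 and 4 adjusted over the list alone, with a median log2 fold change of 0.13. For the chaperone list, camera gave adjusted p = 0.212, or 0.56 with an estimated correlation. The pentose phosphate gene tkt (0.75 ± 0.07) and sqstm1 (1.29 ± 0.13) and gstp1 (1.87 ± 0.21) rose, and hmox1 stood at -0.25 ± 0.1 (edgeR adjusted p = 0.0877). It passed without P3 replicate 0 (0.042) or P1 replicate 1 (0.0352), with adjusted p from 0.0352 to 0.159 over the alternatives. Of 36 oxidative stress genes, 17 rose and 1 fell, or 21 and 4 adjusted over the list alone, with a median log2 fold change of 0.3. For the oxidative stress list, camera gave adjusted p = 2.25e-05, or 0.377 with an estimated correlation. Clock genes per2 (1.44 ± 0.27), cry1a (1.4 ± 0.22), tefa (1.17 ± 0.18) and nfil3-6 (2.16 ± 0.26) rose. In P3 replicate 0 per2 was at 36.66 CPM against 71.97 and 68.63 in the other 2 replicates and 21.79 in the control. Of 44 clock genes, 16 rose and 2 fell, or 17 and 2 adjusted over the list alone, with a median log2 fold change of 0.32. For the clock list, camera gave adjusted p = 0.000347, or 0.347 with an estimated correlation.

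Tailbud genes tbx6 (2.13 ± 0.19) and cyp26a1 (1.15 ± 0.09) and muscle precursor genes myog (1.61 ± 0.13), tmem8c (1.32 ± 0.16) and meox1 (0.95 ± 0.11) rose, and thbs2b (-1.9 ± 0.1) fell. The posterior Hox genes hoxb13a (-1.15 ± 0.21) and hoxd11a (-0.97 ± 0.21), which pattern the tail, fell. Of 53 tailbud and presomitic mesoderm genes, 22 rose and 4 fell, or 22 and 5 adjusted over the list alone, with a median log2 fold change of 0.29. Of 22 myogenic precursor genes, 8 rose and 0 fell, or 8 and 2 adjusted over the list alone, with a median log2 fold change of 0.1. Of 27 posterior Hox genes, 1 rose and 5 fell, or 1 and 9 adjusted over the list alone, with a median log2 fold change of -0.21. For the tailbud and presomitic mesoderm, myogenic precursor and posterior Hox lists, camera gave adjusted p = 0.00133, 0.00479 and 0.0802, or 0.234, 0.124 and 0.456 with an estimated correlation. Without P3 replicate 0, 9 posterior Hox genes fell, and camera called that list and the endoderm and liver list (adjusted p = 0.0453 for both, or 0.319 and 0.479 with an estimated correlation). Of 24 innate immunity genes, 5 rose and 2 fell, or 5 and 2 adjusted over the list alone, with a median log2 fold change of 0.26. Camera called that list without P3 replicate 0 alone (adjusted p = 0.0269 against 0.0867, or 0.32 and 0.448 with an estimated correlation). The myogenic precursor median was then 0.04. The zinc exporter gene slc30a1b (1.51 ± 0.16) rose, while mt2 (-0.97 ± 0.11) and slc30a8 (-1.32 ± 0.11) and the myeloid genes lyz (-1.41 ± 0.15) and mpx (-1.58 ± 0.21) fell. In total 4482 genes (22.6%) changed, 2055 higher and 2427 lower, 1269 of them at least 2-fold. In all 4482 every P3 library lay on the named side of the control, which the call itself favours. DESeq2 gave 2686.

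**Figure D2:**
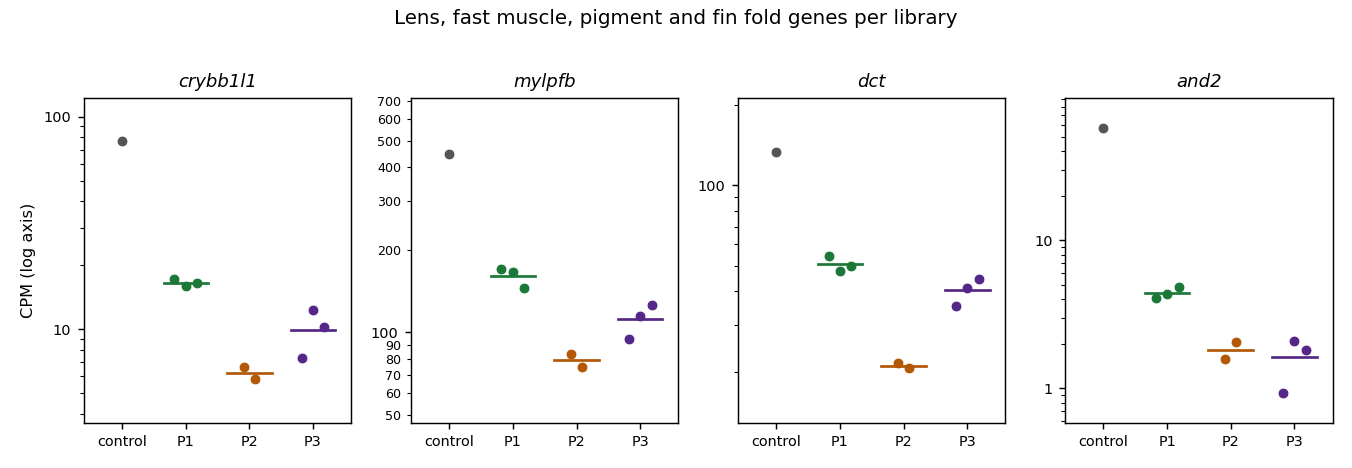
CPM on a log axis of a lens, a fast muscle, a pigment and a fin fold gene in each library, with points for single libraries and lines for the mean of groups with more than 1 library. For and2 the control stood at 57.7 CPM and the means of P1, P2 and P3 at 4.41, 1.82 and 1.62 CPM.

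**Figure D3:**
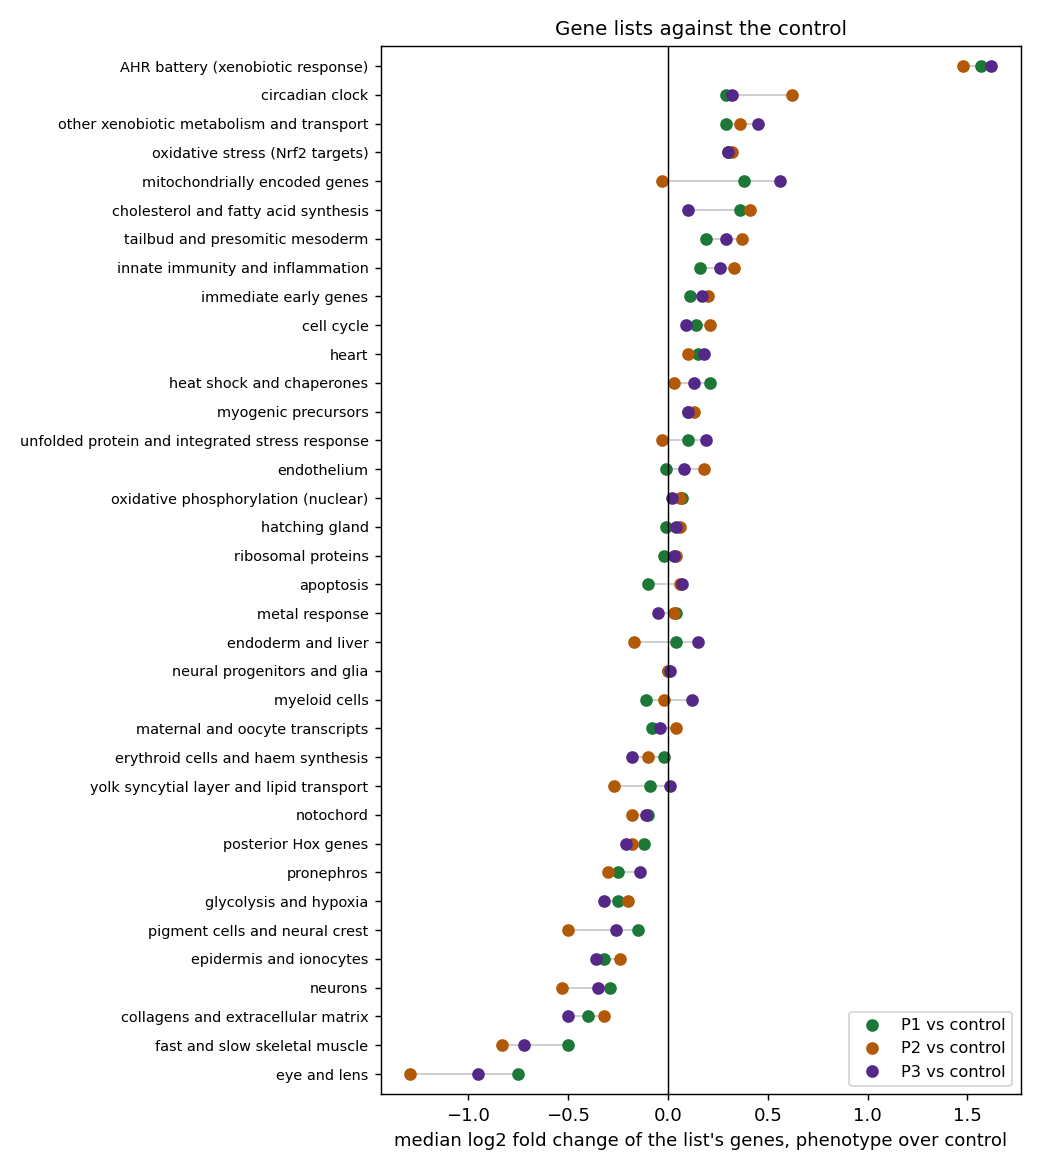
Median log2 fold change against the control of gene lists, with a dot for each phenotype. The eye and lens medians were -0.75 in P1, -1.29 in P2 and -0.95 in P3, and those of the AHR list 1.57, 1.48 and 1.62.

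Much of the change had the same direction in the phenotypes. Against the control 2110 genes changed in all 3, of which 802 were higher, 1303 lower and 5 mixed, and 7463 changed in any. The genes cyp1a, cyp1b1, sult6b1 and tiparp were among those higher, and and2, crybb1l1, mylpfb and dct among those lower. P1 and P2 shared 1068 higher and 1480 lower genes, and 16 were opposite. P2 and P3 shared 1319 higher and 1856 lower, and 39 were opposite. P1 and P3 shared 2490 in the same direction, 1515 of them lower, and 4 were opposite. Independent lists of these sizes would share 200 higher and 284 lower genes for P1 and P2, 292 and 379 for P2 and P3, and 146 and 223 for P1 and P3.

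All 3 comparisons used the same control library, which ties them. In 20 simulations of unchanged groups, the shared control was given the spread of the phenotype replicates. There 76.8% to 78.7% of all genes had the same sign, against 78.3% to 82.2% measured, while shared calls averaged 0.1 to 0.35. Across genes, which are not independent, fold changes of P1 and P2 had a covariance of 0.419 against 0.1157 simulated, and those of P1 and P3 0.3893 against 0.1158. For P2 and P3 it was 0.5088 against 0.1154. The correlations, 0.801 for P1 and P2, 0.88 for P1 and P3 and 0.835 for P2 and P3, lay close to the 0.814, 0.847 and 0.818 simulated, so they show little beyond the shared control. As the control cannot be divided, part of the excess may come from it.

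Deformed-tail embryos (P1) and deformed-yolk embryos (P2) differed in lens, muscle, pigment and chaperone genes, higher in P1, and in single hypoxia and stress genes such as egln3, ankrd37 and PPP1R15A, higher in P2. Of these lists only the pigment call held with an estimated correlation. Values are P1 minus P2. The oxygen sensor gene egln3 (ENSDARG00000032553, chromosome 17, 9776764 to 9794821) was 18.4-fold higher in P2 (-4.2 ± 0.14, edgeR adjusted p = 4.33e-12). It stood at 50.2 ± 0.776 CPM (SD, n = 2) in P2, 2.71 ± 0.222 in P1 (n = 3) and 13.2 in the control. Likewise ankrd37 (-2.75 ± 0.1) and slc16a9a (-3.21 ± 0.13), the stress phosphatase gene PPP1R15A (-1.92 ± 0.07), ddit4 (-1.71 ± 0.1) and mknk2b (-1.54 ± 0.06) and the survival gene mcl1b (-1.46 ± 0.07) were higher in P2. So were the helicase gene ddx43 (-2.48 ± 0.24) and the co-chaperone gene dnajc7 (-1.84 ± 0.13). Higher in P1 were the Z-disc gene tcap (2.71 ± 0.41), the small heat shock gene hspb9 (2.29 ± 0.19), the lens connexin gene cx44.1 (1.93 ± 0.18) and the cone phosphodiesterase gene pde6c (1.67 ± 0.2).

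The gene cyp1a did not pass between P1 and P2 (0.03 ± 0.06, edgeR adjusted p = 0.742), while cyp1b1 (0.44 ± 0.07), cyp1c1 (0.7 ± 0.12) and cyp1c2 (0.87 ± 0.14) were higher in P1. Of 16 AHR genes, 4 were higher in P1 and 1 higher in P2, or 6 and 1 adjusted over the list alone, with a median log2 fold change of 0.14. For the AHR list, camera gave adjusted p = 0.0355, or 0.642 with an estimated correlation. Muscle genes casq1a (1.26 ± 0.1) and mylpfb (1.02 ± 0.1), the lens gene crybb1l1 (1.42 ± 0.15), the pigment genes dct (1.27 ± 0.1), tyrp1b (1.29 ± 0.15) and pmela (0.89 ± 0.11) and the neurofilament gene nefm (1.39 ± 0.1) were higher in P1. Of 75 skeletal muscle genes, 48 were higher in P1 and 4 higher in P2, or 50 and 8 adjusted over the list alone, with a median log2 fold change of 0.45. Of 54 eye and lens genes, 28 were higher in P1 and 0 higher in P2, or 32 and 0 adjusted over the list alone, with a median log2 fold change of 0.63. For the skeletal muscle and eye and lens lists, camera gave adjusted p = 3.24e-17 and 7.11e-15, or 0.335 and 0.155 with an estimated correlation. Of 45 pigment and neural crest genes, 20 were higher in P1 and 2 higher in P2, or 22 and 3 adjusted over the list alone, with a median log2 fold change of 0.27. Of 69 neuron genes, 20 were higher in P1 and 0 higher in P2, or 23 and 1 adjusted over the list alone, with a median log2 fold change of 0.23. For the pigment and neural crest and neuron lists, camera gave adjusted p = 3.32e-08 and 5.7e-06, or 0.0321 and 0.335 with an estimated correlation. The liver genes rbp4 (1.35 ± 0.07) and hnf4a (1.05 ± 0.1) and the prothrombin gene f2 (0.65 ± 0.06) were higher in P1. Chaperone genes hsp47 (1.49 ± 0.18) and dnajb1b (1.0 ± 0.11) and the mitochondrially encoded genes mt-nd2 (0.65 ± 0.08) and mt-nd3 (0.64 ± 0.07) were higher in P1. Of 34 endoderm and liver genes, 15 were higher in P1 and 2 higher in P2, or 16 and 3 adjusted over the list alone, with a median log2 fold change of 0.31. Of 32 chaperone genes, 14 were higher in P1 and 0 higher in P2, or 15 and 0 adjusted over the list alone, with a median log2 fold change of 0.24. Of 13 mitochondrially encoded genes, 12 were higher in P1 and 0 higher in P2, or 12 and 0 adjusted over the list alone, with a median log2 fold change of 0.36. For the endoderm and liver, chaperone and mitochondrially encoded lists, camera gave adjusted p = 1.47e-07, 1.47e-07 and 2.1e-10, or 0.155, 0.155 and 0.164 with an estimated correlation.

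The cell cycle inhibitor gene cdkn1a (-1.03 ± 0.09), the cell death gene bbc3 (-1.09 ± 0.1), the vessel genes stab2 (-0.86 ± 0.07) and cdh5 (-0.48 ± 0.07) and the hypoxia gene cited2 (-0.82 ± 0.08) were higher in P2. Of 35 endothelial genes, 1 were higher in P1 and 16 higher in P2, or 2 and 17 adjusted over the list alone, with a median log2 fold change of -0.25. Of 49 glycolysis and hypoxia genes, 9 were higher in P1 and 8 higher in P2, or 9 and 8 adjusted over the list alone, with a median log2 fold change of -0.03. For the endothelial and glycolysis and hypoxia lists, camera gave adjusted p = 5.57e-06 and 0.000171, or 0.155 and 0.498 with an estimated correlation. Of 35 unfolded protein and integrated stress genes, 14 were higher in P1 and 4 higher in P2, or 15 and 4 adjusted over the list alone, with a median log2 fold change of 0.18. For the unfolded protein and integrated stress list, camera gave adjusted p = 0.196, or 0.642 with an estimated correlation. The clock gene per1b (-0.58 ± 0.07) was higher in P2 and cry2a (0.7 ± 0.06) in P1. Of 44 clock genes, 1 were higher in P1 and 17 higher in P2, or 3 and 19 adjusted over the list alone, with a median log2 fold change of -0.28. For the clock list, camera gave adjusted p = 1.44e-05, or 0.335 with an estimated correlation. The gene hmox1 (0.49 ± 0.08) was higher in P1, as was mt2 (0.46 ± 0.1) (edgeR adjusted p = 0.00256). Without P2 replicate 1 the call of mt2 was lost (edgeR adjusted p = 0.059, range 2.59e-06 to 0.059 over the alternatives).

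In total 4072 genes (20.5%) differed, 2106 higher in P1 and 1966 higher in P2, 657 of them at least 2-fold. In 4069 the P1 and P2 libraries did not overlap, which the call itself favours. DESeq2 gave 2424 genes, and leaving out P2 replicate 0 or 1 gave 1725 or 1848.

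Small embryos (P3) and deformed-tail embryos (P1) had the fewest differing genes of the 3 pairs. More innate immunity and liver genes were higher in P3 than in P1, and more chaperone, matrix, erythroid and lipid synthesis genes higher in P1, though no list call held with an estimated correlation. Values are P3 minus P1. The transporter gene slc16a9a (ENSDARG00000013926, chromosome 17, 20483927 to 20496769) was 5.96-fold higher in P3 (2.57 ± 0.13, edgeR adjusted p = 3.41e-09), at 14.3 ± 1.56 CPM (SD, n = 3) against 2.39 ± 0.339 (n = 3). The bile salt pump gene abcb11a (1.81 ± 0.13), agt (2.08 ± 0.14), the TGF-beta-induced factor gene KLF10 (2.08 ± 0.15), the immune gene irg1l (1.88 ± 0.15) and plekhf1 (1.74 ± 0.14) were higher in P3. So were the cytokine gene tnfb (2.47 ± 0.37), mmp13a (1.07 ± 0.14), the NF-kappaB inhibitor gene nfkbiaa (0.73 ± 0.11) and the complement gene cfb (0.47 ± 0.08). Of 24 innate immunity genes, 5 were higher in P3 and 0 higher in P1, or 5 and 0 adjusted over the list alone, with a median log2 fold change of 0.15. For the innate immunity list, camera gave adjusted p = 0.0055, or 0.338 with an estimated correlation. Higher in P1 were hspb9 (-1.29 ± 0.15) and and1 (-1.08 ± 0.13), the protease gene adamts15a (-1.05 ± 0.15) and the mitochondrial carrier gene slc25a4 (-0.96 ± 0.14).

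The protease inhibitor gene serpina1l (0.88 ± 0.07), rbp2a (1.04 ± 0.09) and the protease gene ctsc (0.96 ± 0.08) were higher in P3, and rbp4 (-0.82 ± 0.06) in P1. Of 34 endoderm and liver genes, 10 were higher in P3 and 1 higher in P1, or 16 and 2 adjusted over the list alone, with a median log2 fold change of 0.2. Of 44 yolk and lipid transport genes, 18 were higher in P3 and 6 higher in P1, or 21 and 8 adjusted over the list alone, with a median log2 fold change of 0.12. For the endoderm and liver and yolk and lipid transport lists, camera gave adjusted p = 8.58e-05 and 0.0261, or 0.338 and 0.338 with an estimated correlation. The elongase gene elovl2 (-0.91 ± 0.12), the sterol demethylase gene cyp51 (-0.95 ± 0.16), rhag (-0.45 ± 0.07) and the transferrin receptor gene tfr1a (-0.43 ± 0.07) were higher in P1. Of 35 lipid synthesis genes, 4 were higher in P3 and 15 higher in P1, or 4 and 20 adjusted over the list alone, with a median log2 fold change of -0.28. Of 32 erythroid genes, 1 were higher in P3 and 11 higher in P1, or 1 and 15 adjusted over the list alone, with a median log2 fold change of -0.2. For the lipid synthesis and erythroid lists, camera gave adjusted p = 1.57e-05 and 2.38e-06, or 0.268 and 0.268 with an estimated correlation. Lens genes cryba2b (-0.68 ± 0.09) and crybb1 (-0.69 ± 0.11) and muscle genes casq1a (-0.73 ± 0.08) and acta1b (-0.5 ± 0.06) were higher in P1, with P3 replicate 0 below the other P3 libraries in the muscle list. Of 54 eye and lens genes, 0 were higher in P3 and 15 higher in P1, or 0 and 21 adjusted over the list alone, with a median log2 fold change of -0.28. Of 75 skeletal muscle genes, 1 were higher in P3 and 22 higher in P1, or 2 and 39 adjusted over the list alone, with a median log2 fold change of -0.18. For the eye and lens and skeletal muscle lists, camera gave adjusted p = 3.2e-09 and 1.65e-09, or 0.268 and 0.423 with an estimated correlation. Without P3 replicate 0, 5 muscle genes were higher in P3 and 18 in P1, with a median of -0.1 (camera adjusted p = 2.99e-05, or 0.464 with an estimated correlation). Mitochondrially encoded genes mt-cyb (0.27 ± 0.05) and mt-nd2 (0.32 ± 0.07) were higher in P3. Of 13 mitochondrially encoded genes, 8 were higher in P3 and 0 higher in P1, or 11 and 0 adjusted over the list alone (median 0.19). For the mitochondrially encoded list, camera gave adjusted p = 1.63e-05, or 0.338 with an estimated correlation.

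The sestrin genes sesn2 (0.6 ± 0.08) and sesn3 (0.6 ± 0.06), the zinc exporter gene slc30a1b (1.12 ± 0.1) and the glucose transporter gene slc2a1a (0.7 ± 0.09) were higher in P3, and the chaperonin gene hspd1 (-0.28 ± 0.05) in P1. Of 32 chaperone genes, 0 were higher in P3 and 7 higher in P1, or 2 and 8 adjusted over the list alone, with a median log2 fold change of -0.11. Of 70 collagen and matrix genes, 1 were higher in P3 and 15 higher in P1, or 1 and 23 adjusted over the list alone, with a median log2 fold change of -0.12. For the chaperone and collagen and matrix lists, camera gave adjusted p = 0.00217 and 2.45e-06, or 0.338 and 0.403 with an estimated correlation. Without P3 replicate 0, 12 chaperone genes were higher in P1 and 8 innate immunity genes higher in P3 (camera adjusted p = 1.48e-06 and 5.16e-05, or 0.291 for both with an estimated correlation). None of 4 AHR cytochrome genes passed in edgeR, cyp1a at 0.01 ± 0.05 (adjusted p = 0.952), cyp1b1 at -0.14 ± 0.06 (0.153), cyp1c1 at -0.33 ± 0.11 (0.0532) and cyp1c2 at -0.22 ± 0.12 (0.283). With no filter, at the control total, or without P3 replicate 1 (0.0217) or 2 (0.0425), cyp1c1 passed, with adjusted p from 2.46e-05 to 0.308 over the alternatives. In total 2069 genes (10.4%) differed, 1192 higher in P3 and 877 higher in P1, 211 of them at least 2-fold. In 2026 the groups did not overlap, which the call itself favours. DESeq2 gave 1246 genes, and leaving out P1 replicate 0 gave 1301.

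Small embryos (P3) and deformed-yolk embryos (P2) differed in the liver, yolk, lens, muscle, mitochondrially encoded and unfolded protein and integrated stress lists, higher in P3. Clock genes and single hypoxia and stress genes such as egln3, PPP1R15A and ddit4 were higher in P2. No list call held with an estimated correlation. Values are P3 minus P2. The gene egln3 (ENSDARG00000032553, chromosome 17, 9776764 to 9794821) was 13.7-fold higher in P2 (-3.78 ± 0.13, edgeR adjusted p = 9.61e-12), at 3.6 ± 1.18 CPM (SD, n = 3) in P3 against 50.2 ± 0.776 (n = 2). With it ankrd37 (-2.58 ± 0.09), ddx43 (-1.59 ± 0.21), PPP1R15A (-1.48 ± 0.07), mcl1b (-1.23 ± 0.07), ddit4 (-1.02 ± 0.09) and mknk2b (-1.01 ± 0.06) and the co-chaperone gene fkbp5 (-1.55 ± 0.2), known for its induction by glucocorticoids, were higher in P2. Higher in P3 were the adenosine receptor gene adora2ab (2.28 ± 0.28), the kinase gene mknk2a (2.14 ± 0.12), the uncoupling protein gene ucp1 (2.06 ± 0.13) and the bile salt pump gene abcb11a (2.03 ± 0.15). So was the collagen chaperone gene hsp47 (1.89 ± 0.18).

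Liver genes serpina1l (1.33 ± 0.08), hnf4a (1.26 ± 0.1) and f2 (1.03 ± 0.06) and the transferrin gene tfa (0.83 ± 0.07) were higher in P3. Of 34 endoderm and liver genes, 17 were higher in P3 and 0 higher in P2, or 20 and 0 adjusted over the list alone (median 0.5). Of 44 yolk and lipid transport genes, 22 were higher in P3 and 5 higher in P2, or 22 and 5 adjusted over the list alone (median 0.25). For the endoderm and liver and yolk and lipid transport lists, camera gave adjusted p = 1.81e-16 and 2.71e-09, or 0.0751 and 0.0751 with an estimated correlation. Mitochondrially encoded genes mt-nd2 (0.96 ± 0.08) and mt-co3 (0.58 ± 0.05) and the melanin gene dct (0.94 ± 0.1) were higher in P3. Of 13 mitochondrially encoded genes, 13 were higher in P3 and 0 higher in P2, or 13 and 0 adjusted over the list alone (median 0.58). Of 45 pigment and neural crest genes, 16 were higher in P3 and 2 higher in P2, or 18 and 2 adjusted over the list alone (median 0.2). For the mitochondrially encoded and pigment and neural crest lists, camera gave adjusted p = 1.96e-21 and 6.35e-06, or 0.0791 and 0.0733 with an estimated correlation. Camera also called the muscle, lens and neuron lists higher in P3 (adjusted p = 0.000227, 0.00101 and 0.00115). It called the matrix list higher in P2 (4.27e-06). The sterol genes insig1 (-1.2 ± 0.11) and idi1 (-0.66 ± 0.07) and the hypoxia gene cited2 (-0.73 ± 0.07) were higher in P2. Of 35 lipid synthesis genes, 5 were higher in P3 and 15 higher in P2, or 5 and 19 adjusted over the list alone (median -0.34). Of 49 glycolysis and hypoxia genes, 4 were higher in P3 and 9 higher in P2, or 6 and 10 adjusted over the list alone (median -0.04). For the lipid synthesis and glycolysis and hypoxia lists, camera gave adjusted p = 0.000203 and 8.07e-05, or 0.208 and 0.439 with an estimated correlation. Without P3 replicate 0, 9 hypoxia list genes were higher in P3 and 8 in P2, with a median log2 fold change of 0.04 and camera still pointing to P2 (adjusted p = 0.00421, or 0.402 with an estimated correlation).

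The clock gene per1b (-0.48 ± 0.07) was higher in P2 and cry2a (0.77 ± 0.06) in P3, where replicate 0 lay below the other libraries in per2. Of 44 clock genes, 2 were higher in P3 and 19 higher in P2, or 2 and 22 adjusted over the list alone (median -0.34). Of 35 unfolded protein and integrated stress genes, 18 were higher in P3 and 2 higher in P2, or 21 and 2 adjusted over the list alone (median 0.24). Of 32 chaperone genes, 11 were higher in P3 and 1 higher in P2, or 11 and 3 adjusted over the list alone (median 0.08). For the clock, unfolded protein and integrated stress and chaperone lists, camera gave adjusted p = 9.56e-06, 0.000319 and 0.00502, or 0.349, 0.338 and 0.439 with an estimated correlation. The cell cycle inhibitor gene cdkn1a (-1.05 ± 0.09) and the cell death gene bbc3 (-0.71 ± 0.1) were higher in P2, and the kidney cotransporter gene slc12a1 (1.61 ± 0.14) and dnajb1b (1.03 ± 0.11) and mt2 (0.5 ± 0.09) in P3. Expression of cyp1a did not pass (0.04 ± 0.06, edgeR adjusted p = 0.676), while cyp1b1 (0.3 ± 0.07), cyp1c1 (0.37 ± 0.12) and cyp1c2 (0.66 ± 0.14) were higher in P3. Over the alternatives their adjusted p ran from 9.38e-05 to 0.0655, 3.26e-06 to 0.245 and 4.19e-09 to 0.0697. Calls were lost without P2 replicate 0 (log2 fold changes 0.29, 0.4 and 0.59) and, for cyp1b1 and cyp1c1, without P2 replicate 1 (0.3 and 0.34). The cyp1c1 call was lost without P3 replicate 1 or 2 (adjusted p 0.14 and 0.131), with a replicate block (0.111) or with DESeq2 (0.245). In total 4270 genes (21.5%) differed, 2178 higher in P3 and 2092 higher in P2, 575 of them at least 2-fold. In 4241 the groups did not overlap, which the call itself favours. DESeq2 gave 2614 genes, and leaving out P2 replicate 0 or 1 gave 1885 or 1903.

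**Figure D4:**
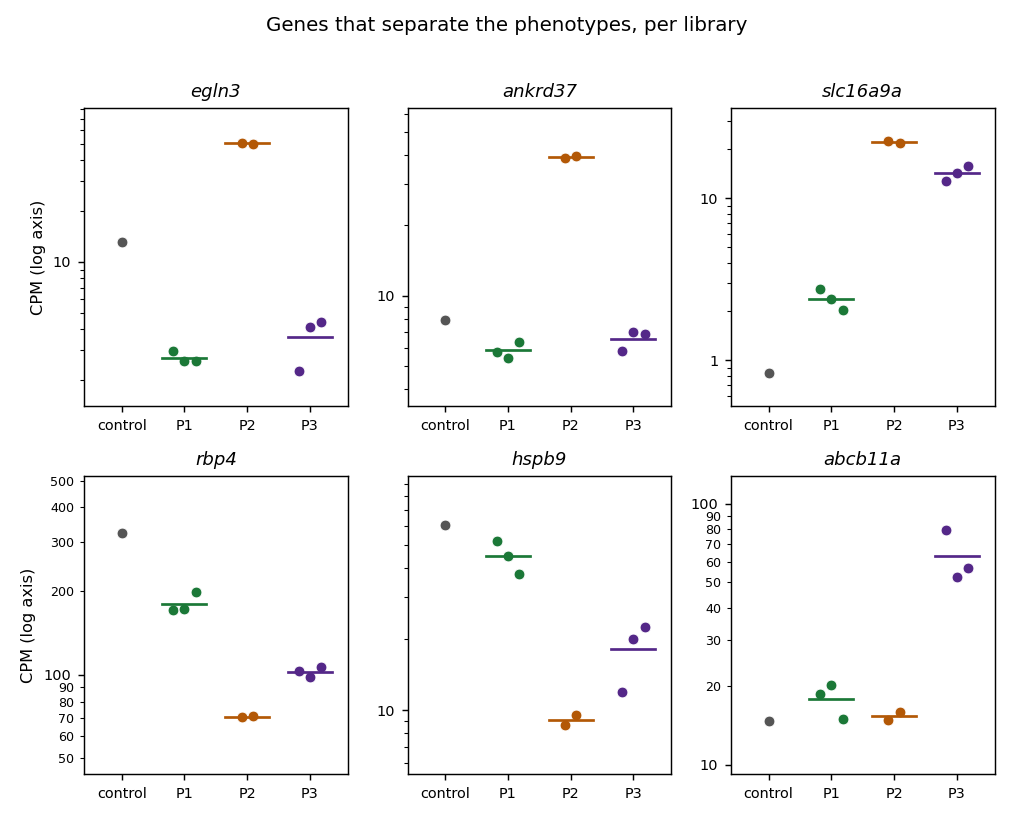
CPM on a log axis of genes that differed between phenotypes, with points for single libraries and lines for the mean of groups with more than 1 library. For ankrd37 the means of P1, P2 and P3 were 5.84, 39.2 and 6.56 CPM.

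A joint edgeR test of any difference among P1, P2 and P3 called 5708 genes (28.8%), and 3083 or 3145 when P2 replicate 0 or 1 was left out. For gene lists, camera compares a list with all other tested genes. Fry tests whether the genes of a list move, on balance, in a single direction, and compares it with no other list. Of 37 lists, camera called 23, 19 and 20 in P1, P2 and P3 against the control, of which 4, 3 and 3 held with an estimated correlation, and fry called 25, 23 and 25. The AHR, eye and lens, and pigment lists held in all 3 phenotypes, and the epidermis and ionocyte list in P1. Between phenotypes camera called 18, 16 and 19 lists for P1 and P2, P3 and P1, and P3 and P2, of which 1, 0 and 0 held, the pigment list for P1 and P2.

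**Figure D5:**
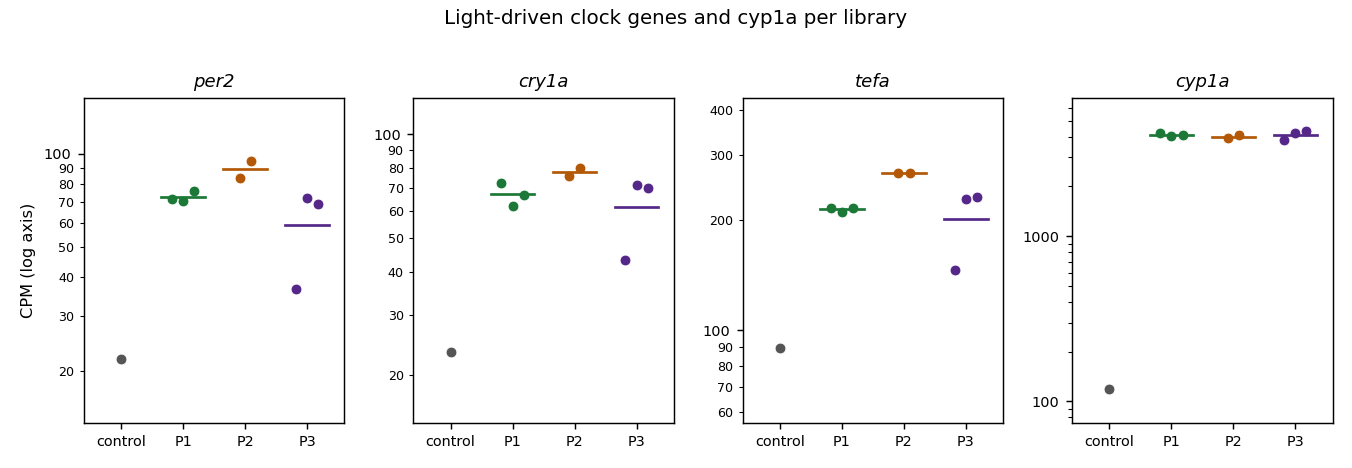
CPM on a log axis of clock genes and cyp1a in each library, with points for single libraries and lines for the mean of groups with more than 1 library. For per2 the control stood at 21.79 CPM, P3 replicate 0 at 36.66 CPM and the other 2 P3 replicates at 71.97 and 68.63 CPM.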

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

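The test against a 2-fold minimum and the test of other splits were chosen after the comparisons had been seen. Each gene given here differed between 2 phenotypes by more than 2-fold (edgeR's glmTreat, adjusted p below 0.05). In all, 82, 12 and 55 genes did so for P1 and P2, P3 and P1, and P3 and P2. The genes named are those among them that the naming rule had picked. The control library does not enter the difference, which compares malformation groups that were all exposed.

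As P1 minus P2 on the log2 scale, hypoxia genes egln3 (-4.20) and ankrd37 (-2.75), the transporter gene slc16a9a (-3.21) and the helicase gene ddx43 (-2.48) had higher values in P2. Stress and survival genes PPP1R15A (-1.92), dnajc7 (-1.84), ddit4 (-1.71), mknk2b (-1.54) and mcl1b (-1.46) did too. Muscle, lens and chaperone genes tcap (2.71), mipb (2.3), hspb9 (2.29) and cx44.1 (1.93) had higher values in P1, as did C6H17orf67 (1.75), and1 (1.58), nefm (1.39) and rbp4 (1.35).

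As P3 minus P1, slc16a9a (2.57), agt (2.08), KLF10 (2.08), irg1l (1.88), abcb11a (1.81) and plekhf1 (1.74) had higher values in P3. As P3 minus P2, egln3 (-3.78), ankrd37 (-2.58) and PPP1R15A (-1.48) had higher values in P2. Higher in P3 were adora2ab (2.28), mknk2a (2.14), ucp1 (2.06), abcb11a (2.03), hsp47 (1.89), ctssb.1 (1.87), C6H17orf67 (1.76), slc12a1 (1.61), agt (1.6), nefm (1.39) and serpina1l (1.33).

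With 1 to 3 libraries per group, no test for a library far from the rest of its group was applied. The 6 libraries of P3 and P1 can be split 3 against 3 in 10 ways, too few for a share under 0.1, and the real split gave 2069 genes, as many or more in 1 of the 10 splits, with 0 as the highest of the others.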

How the results depend on the processing

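Thinning all libraries to the total of the control and list tests without P3 replicate 0 were chosen after seeing the data, and the other alternatives were not. RLE size factors, library totals alone, no filter, a filter of 1 CPM in 2 libraries and a fit of the 2 groups alone left every count of changed genes they were run for within 1.5 times its value, as did thinning, which gave 3208, 5538 and 4296 genes for P1, P2 and P3 against the control, 3499, 1783 and 3648 for P1 and P2, P3 and P1, and P3 and P2, and 4888 for any difference. Library totals alone, a filter of 1 CPM in 2 libraries, a fit of 2 groups and the 2-fold minimum were not run for any difference.

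DESeq2 gave 1913, 3769 and 2686 genes against the control, where edgeR gave 3227, 5916 and 4482, and 2424, 1246 and 2614 between phenotypes, where edgeR gave 4072, 2069 and 4270; for any difference it gave 3870 against 5708. The cause was not tested. Requiring a 2-fold change left 706, 1786 and 1269 genes against the control and 657, 211 and 575 between phenotypes, by its construction, and moved the share called higher from 43.5% to 31.2% in P1, from 47.7% to 31.2% in P2, from 57.6% to 71.1% for P3 against P1 and from 51% to 67.7% for P3 against P2. Genes called the same way in 2 comparisons with the control fell from 2548 to 563 for P1 and P2, from 2490 to 579 for P1 and P3, and from 3175 to 917 for P2 and P3.

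Leaving out each phenotype replicate in turn gave 2369 to 4208 genes for P1, 3981 to 6815 for P2 and 3963 to 4673 for P3 against the control, 1725 to 5206 for P1 and P2, 1301 to 2156 for P3 and P1, 1885 to 4654 for P3 and P2, and 3083 to 6536 for any difference. Each of these highest values came without P3 replicate 0. Counts moved by more than 1.5 times without P2 replicate 0 or 1 (1725 and 1848 for P1 and P2, 1885 and 1903 for P3 and P2, 3083 and 3145 for any difference) and without P1 replicate 0 (1301 for P3 and P1). With 1 P2 library left, that library is assumed to vary like the other groups.

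No paired analysis against the control was possible because it is 1 pooled library, whose number is only a name. Between phenotypes a replicate block gave 3070 genes for P1 and P2, 1676 for P3 and P1, 3243 for P3 and P2 and 4388 for any difference. Deviations from group means correlated across genes at -0.107 to 0.018 for same-numbered libraries and -0.047 to 0.101 for others. In groups this small deviations depend on each other, so pairing cannot be excluded.

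With an estimated correlation, camera called 4, 3 and 3 lists against the control where the preset one called 23, 19 and 20, and 1, 0 and 0 between phenotypes where it called 18, 16 and 19; fry called 14, 13 and 15 there. Of 222 list results, 118 kept their side of the threshold with an estimated correlation and 104 lost their call, and with fry 188 kept it, 17 lost and 17 gained a call. The cause was not tested. Without P3 replicate 0 camera called 23, 18 and 19 lists for P3 against the control, P1 and P2, and of 111 list results 98 kept their side of the threshold, 4 lost and 9 gained a call. Among the gains were the AHR list for P3 and P2 (adjusted p from 0.241 to 0.00703) and the other xenobiotic list for P3 and P1 (0.149 to 0.00272) and P3 and P2 (0.0694 to 0.0022), at 0.331, 0.291 and 0.165 with an estimated correlation. Lists were not tested without the other replicates.

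Of 351 gene results picked by the naming rule (160 genes), 331 passed, and 333 kept their sign and side of the threshold under all alternatives run except the 2-fold minimum. DESeq2 gave no adjusted p for 5, and 10 were removed by an alternative filter. No gene or list result reversed.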

Other observations

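Several groups had no camera call against the control. Fry called metal response genes lower in P1, P2 and P3 (adjusted p = 0.011, 0.00963 and 0.0273). It called apoptosis genes higher in P2 (0.0155) and heart genes higher in P3 (0.0339). Ribosomal protein genes (73 tested) had 0 higher and 1 lower in P1, 5 and 0 in P2, and 0 and 0 in P3, or 0 and 0 in each adjusted over the list alone (camera adjusted p = 0.87, 0.246 and 0.51). Genes of neural progenitors and glia (65 tested) had 3 higher and 4 lower in P1, 12 and 15 in P2, and 10 and 10 in P3, or 3 and 4, 15 and 17, and 12 and 14 adjusted over the list alone (camera adjusted p = 0.87, 0.945 and 0.946). Heart genes (35 tested) had 4 and 2, 7 and 6, and 11 and 4, or 5 and 2, 9 and 6, and 11 and 5 adjusted over the list alone (camera adjusted p = 0.156, 0.353 and 0.0802). Nuclear genes of oxidative phosphorylation (67 tested) had 3 and 2, 5 and 3, and 2 and 2, or 0 and 2, 2 and 2, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.0959, 0.353 and 0.635). Maternal and oocyte transcripts (20 tested) had 2 and 1, 1 and 1, and 1 and 3, or 2 and 1, 0 and 0, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.932, 0.891 and 0.715). Metal response genes (12 tested) had 0 and 3, 2 and 2, and 1 and 2, or 2 and 3, 2 and 2, and 1 and 3 adjusted over the list alone (camera adjusted p = 0.12, 0.292 and 0.294). Apoptosis genes (26 tested) had 2 and 1, 3 and 1, and 4 and 1, or 2 and 1, 3 and 0, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.985, 0.0858 and 0.217).

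The tests of handling, of a rise through the extract, of the control library's level and of slower development were chosen after the result was seen. Clock genes that rose in P1 and P2 (in a fit without P3) were low in P3 replicate 0 as well: 15 of 15 lay below both other P3 replicates, by a median log2 of -0.65. Control RNA mixed into that library would need a share of 71.7% (57.8 to 79.5) for the clock genes but 19% (3.5 to 34.5) for the AHR genes, which argues against it. Handling of single libraries before lysis, such as light or the hour, and a rise through the extract cannot be told apart, since the count of 15 restates the pattern, 14 of the 15 lay above the control in that library, and there was 1 control library. P3 replicate 0 also lay below the other P3 replicates in muscle (median log2 difference -0.39), innate immunity (-0.21), hypoxia (-0.18), matrix (-0.17), oxidative stress (-0.15), erythroid (-0.14) and neuron genes (-0.14), each at percentile 0 of matched random lists, in other xenobiotic (-0.22), AHR (-0.19) and lens genes (-0.12), at percentile 0.15, 0.05 and 0.1, and above them in mitochondrially encoded genes (0.15).

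Of 241 tested genes of the lens, muscle, pigment and neuron lists, 108 fell in all 3 phenotypes, and 115, 163 and 138 in P1, P2 and P3. With all libraries at the control total, 112 of 115, 159 of 163 and 135 of 138 still fell (97.4% at the lowest). The falls thus did not rest on the greater depth of the exposed libraries. Thinning left the control counts as they were, so it cannot test error from the control's own depth. The control library's level cannot be told apart as the source of the common fall, with 1 control library. Among P1, P2 and P3, a comparison that does not use the control, 120 of the 241 differed. Slower development cannot be told apart either: the tailbud and presomitic mesoderm medians lay at percentile 99.99 or above in matched random lists in all 3 phenotypes, but such lists ignore correlation between genes, and camera with an estimated correlation gave adjusted p = 0.196, 0.167 and 0.234. A loss of these tissues was not tested.

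The authors' tables hold 2261, 4477 and 2393 genes below an adjusted p of 0.05 for P1, P2 and P3 (901 and 1360, 2045 and 2432, and 900 and 1493 higher and lower), and 1419, 3124 and 1596 below 0.01. With a 2-fold minimum on the authors' variance-corrected ratio 31, 36 and 130 remain. The edgeR calls include 2162, 4222 and 2370 of those below 0.05 (95.6%, 94.3% and 99%), each with the same sign.

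Near-absent genes, at least 6-fold below every other library throughout a group and at 0.5 CPM or more elsewhere, were counted after values had been seen, and a group of 2 libraries meets this more often by chance. P1 had 1 (CABZ01044356.1, at most 0.174 CPM against 2.34 to 6.21), P2 had 9, such as HPX (1 of 2) (at most 0.122 CPM against 1.5 to 7.68) and gpr112 (0.122 against 0.748 to 1.63), and P3 had 0.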
